A study of Mus musculus with 18 samples.

How the data were processed

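RNA was measured in 18 libraries, 3 for each of 6 germ cell populations sorted from mouse testes. Per the labels' protocols, cells of adult mice carrying the Stracre-GAG-tdTomato transgenes were sorted on an Aria 3, RNA was made with a Qiagen kit and DNase, and indexed libraries were pooled and read single-end on a HiSeq 2500. The deposited values are counts of reads per gene made by the authors and not scaled, as whole numbers with a different total in each library. Per the submitters' processing notes, cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and GRCm38 were used, without the role or order of each. The annotation release, the strand setting and any filters are not given in the sources used here. Reads carry no molecular identifiers, so copies made by PCR are counted as reads, and floors and counting intervals cover counting error only.

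The table holds 46603 Ensembl mouse gene IDs, and 46091 of them (98.9%) were found in GENCODE M21 on GRCm38, which gave names, classes and coordinates. The other 512 took 0.048% to 0.11% of reads per library and were kept under their IDs. Totals ran from 11777947 to 16607462 counts per library. Near-identical genes such as Pgk1, Gapdh, ribosomal protein genes and MHC genes share reads in ways the counts do not show, so their levels are uncertain. Groups and replicate numbers were taken from the labels. Each pair of replicates was tested for being copies of each other, and differed by 2.38 to 47.3 times the counting variance; correlations of log2 CPM within groups were 0.961 to 0.993.

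Genes were kept by filterByExpr with the 6 groups, which left 18547. Counts were scaled by TMM and fitted with edgeR 4.0.16 under R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest, 2-sided, 1 model of the 6 groups), with a common biological coefficient of variation of 0.2025. Tests were made for any difference among groups and for the 5 steps Diff.Spg against Undiff.Spg, PreL against Diff.Spg, LZ against PreL, PD against LZ and RS against PD, with Benjamini-Hochberg adjustment within each. A gene was called at adjusted p under 0.05 and at least 2-fold; for the named genes and list members the fold condition was left out. A gene was enriched in a group when it was called higher than in each of the 5 others. CPM use TMM-scaled totals. A standard error is the absolute log2 fold change over the square root of the F statistic. A gene with no read in a group is compared with a floor of 3 reads over the group's 3 libraries and given as a bound. Medians at the bounds leave out genes at or under this floor in both groups.

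Lists of genes for germ cell stages, pathways, sex chromosomes and other testis cell types were written from general knowledge, not from these data, and 29 of them had at least 3 tested members. They were tested by camera of limma 3.58.1 on log2 CPM (prior count 2) with a correlation between genes of 0.01, adjusted over all lists and the 5 steps. Beside each call stands the same test with the correlation estimated from the libraries, and the members called after adjusting over all genes and over the list alone. Some genes stand in several lists, Stra8 among them, so the lists are not independent. The X-linked genes were compared with autosomal genes in the same way, adjusted over the 5 steps; counts of X-linked and Y-linked genes carry the 2-fold condition. Shares of chromosomes and of gene classes among enriched genes were compared by Fisher's exact test.

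The comparisons, lists, named genes and alternatives were fixed before the data were examined. Named genes are, for each step, up to 13 genes chosen in advance whatever their result, the 5 largest rises and 5 largest falls with a mean of at least 50 CPM in the higher group (leaving out predicted, Riken and mitochondrial genes), and up to 4 members of each called list in its main direction and 2 in the other. For each enriched set the 5 most abundant genes are named. List members are also named where their list is described. Some of the genes chosen by these rules are not reported here. The measures of late transcripts in earlier libraries, of RS transcripts in PD and of X-linked genes under 1% of their LZ level, the gene classes of enriched genes, and the left-out pair PreL replicate 2 and LZ replicate 2 were chosen after the values were seen.

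Alternatives were RLE scaling, total library size only, no low-count filter, a filter of 1 CPM in 3 libraries, replicate number as a block, each library left out in turn, DESeq2 1.42.0, each pair of groups fitted alone, no fold condition, and the estimated correlation for lists. Replicate numbers were tested for pairing by correlating the deviations of libraries from their group means. The same numbers stood at 0.455, 0.683 and 0.254 between PreL and LZ, and at 0.228, 0.445 and 0.121 between Diff.Spg and PreL. Diff.Spg replicate 3 and LZ replicate 3 correlated more with PreL replicate 1 (0.193 and 0.286). Between Undiff.Spg and Diff.Spg the same numbers stood at 0.02, 0.251 and 0.149, each the highest for its Undiff.Spg library. This match is partial, and none was seen between LZ and PD or between PD and RS. The pipeline was tested on simulated data made from the Undiff.Spg and Diff.Spg counts of 18195 genes, with 50 genes changed at each fold. It called 16% at 1.5-fold, 58% at 2-fold, 94% at 4-fold and 98% at 8-fold, and 1 unchanged gene (0.006%). These shares are of genes at adjusted p under 0.05 in the right direction, without the 2-fold condition. Changes near or under 2-fold are thus often missed. The reported counts also need an observed fold of at least 2, so they miss no fewer. Of 28 simulated lists without change 0 were called, and a changed list of 25 genes was called. The simulated genes varied independently and the unchanged lists were random. The real lists had estimated correlations between genes of up to 0.969, so this simulation cannot show how often such lists are called falsely. Tables were prepared with Python 3.11.15 and figures drawn with matplotlib 3.10.9. Splicing, transposons and single cells were not analysed here.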

Results

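Read counts per gene were analysed for 18 RNA-seq libraries of germ cells sorted from testes of adult C57BL/6 mice that carry a Cre transgene and a tdTomato reporter. The libraries form 6 groups of 3, called here by their labels, Undiff.Spg, Diff.Spg, PreL, LZ, PD and RS. The labels do not spell these names out. In this field they usually stand for undifferentiated and differentiating spermatogonia, preleptotene, leptotene and zygotene, pachytene and diplotene spermatocytes, and round spermatids. Of 46603 genes, 18547 were expressed enough to test. Levels are CPM, counts scaled to a common library total, mean ± SD of 3 libraries (n = 3 in every group), and log2 fold changes carry their SE. Adjusted p-values of genes come from edgeR. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

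Each population has transcripts that set it apart, taken here as genes at least 2-fold higher than in every other group. Undiff.Spg had 1345 such genes, led by Trrap (1283 ± 159 CPM), Tubb5 (949 ± 36.9) and Txnip (857 ± 22.8). Egr4 (854 ± 24.1), an immediate early gene, and Srebf2 (836 ± 13.2) came next. Diff.Spg had 268, with Sox12 (354 ± 10.7) and the retinoic acid binding protein gene Crabp1 (319.9 ± 13.0) the most abundant. Plxnd1 (267 ± 22.9), Grb10 (240.1 ± 8.69) and Ptp4a3 (219.8 ± 7.10) followed. PreL had 50, with the X-linked homeobox gene Esx1 at 754 ± 163 CPM against 287 in the next group. Ptms (298 ± 62.0), Melk (196 ± 36.5), E2f2 (138 ± 24.4) and Pou4f1 (106 ± 24.2) were the next in level. LZ had 840, led by the chaperone gene Hspa5 (2939 ± 389), Tex101 (1927 ± 248) and Tex15 (1702 ± 157). Prss50 (1671 ± 346) and the meiotic cohesin gene Smc1b (1193 ± 148) were also among its 5 highest. PD had 790, with the glucose transporter gene Slc2a3 at 6449 ± 338 CPM. Piwil1 stood there at 1992 ± 421 CPM against 115 in the next group, Atxn7l3b at 1747 ± 121 and Calm2 at 1392 ± 191, all among its 5 highest. RS had 2623, led by the anchoring protein gene Akap12 (4900 ± 208), Hk1 (2117 ± 153) and Tex2 (1844 ± 88.3). The sperm fibrous sheath gene Akap3 (1810 ± 256) and Spata21 (1787 ± 217) completed its first 5.

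Of the 18547 tested genes, 18365 (99.0%) differed among the 6 groups. X-linked genes made up 10.4% of the LZ-enriched genes (87 of 840, Fisher's exact adjusted p = 2.78e-15) and 6.86% of the RS-enriched genes (180 of 2623, adjusted p = 3.91e-13). None of the 790 PD-enriched genes was X-linked (adjusted p = 1.93e-14), against 4.04% of all tested genes. Long non-coding RNA genes made up 22.7% of the PD-enriched and 23.2% of the RS-enriched genes (adjusted p = 7.07e-22 and 9.61e-87), against 10.9% of all tested genes. They made up 5.95% of the Undiff.Spg-enriched genes (80 of 1345, adjusted p = 2.34e-10) and 0 of 50 in PreL (adjusted p = 0.0079). The PreL count was 79 without PreL replicate 2.

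**Figure D1:**
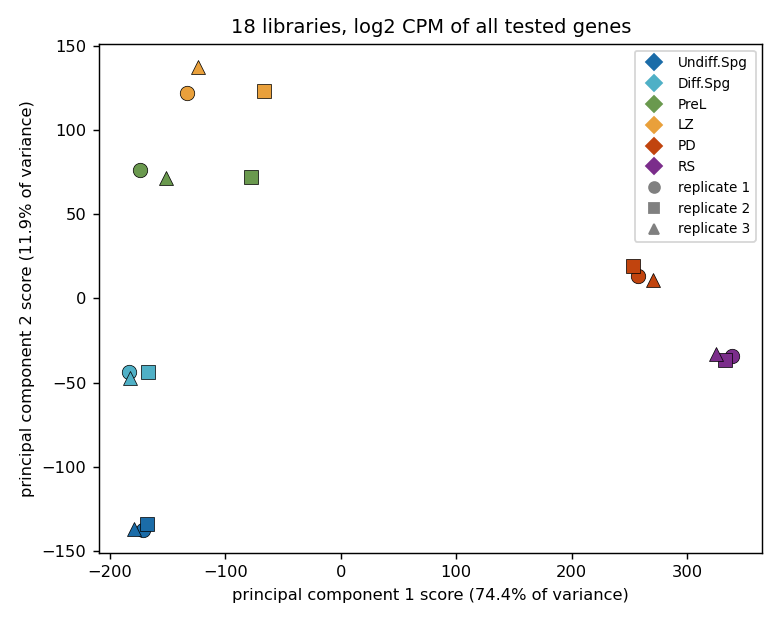
The 18 libraries (points; colour, group; shape, replicate number) on the first principal components of log2 CPM. The first axis holds 74.4% of the variance and parts PD and RS from the 4 other groups, and the second holds 11.9%.

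PreL replicate 2 and LZ replicate 2 hold more late germ-cell transcripts than the other libraries of their groups. Over 179 genes abundant in PD and RS and near absent before, PreL replicate 2 stood at a median of 3.3% of the mean PD and RS level (quartiles 3.1 and 3.55). LZ replicate 2 stood at 3.25% (2.87 and 3.72). The medians were 0.351% and 0.708% in the other PreL libraries and 0.32% and 0.517% in the other LZ libraries. The Undiff.Spg and Diff.Spg libraries, low by this choice, stood at 0.0995% to 0.344%. Changes of late genes such as Ldhc that involve PreL or LZ are given below also without these libraries. RS transcripts were measured in PD in the same way. Over 120 X-linked genes at 20 CPM or more in RS, the 3 PD libraries stood at medians of 9.57% (quartiles 8.27 and 11.4), 6.53% (5.63 and 7.49) and 8.46% (6.77 and 10.1) of the RS level. For X-linked genes active in LZ (49 genes) the medians were 9.5%, 6.56% and 8.41%, and for those low in LZ (52 genes) 9.85%, 6.57% and 8.56%. Over 6491 autosomal genes the 1st percentile was 7.89%, 5.5% and 7.02%.

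**Figure D2:**
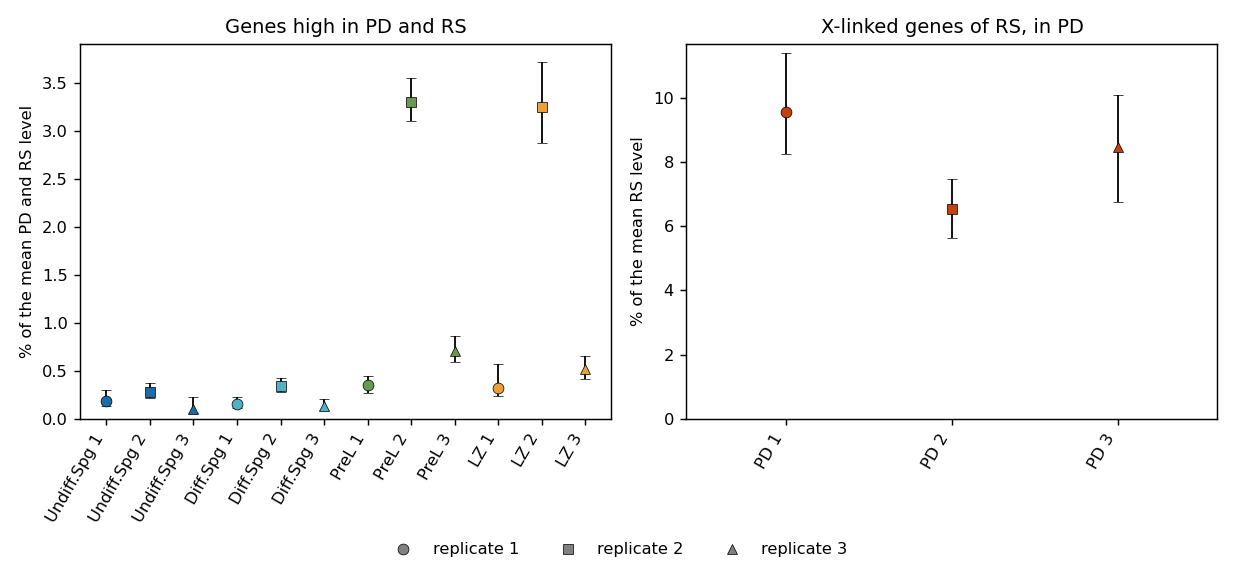
Late transcripts in earlier libraries (points, median over genes; bars, quartiles). Left, 179 genes (low in Undiff.Spg and Diff.Spg by choice) as percent of their mean PD and RS level in the 12 libraries before PD. In PreL and LZ replicate 2 is highest (3.3% and 3.25%). Right, 120 X-linked genes as percent of their RS level in the 3 PD libraries (9.57%, 6.53% and 8.46%).

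From Undiff.Spg to Diff.Spg, the genes of the stem and progenitor state fall. Gfra1, which encodes the co-receptor for GDNF, fell 28.4-fold, from 228 ± 29.5 to 8.0 ± 2.81 CPM (log2 fold change −4.83 ± 0.38, adjusted p = 3.97e-08). It is ENSMUSG00000025089, chromosome 19, 58235604 to 58455909 on GRCm38. The GDNF receptor gene Ret fell from 582 ± 54.4 to 18.2 ± 5.67 CPM (log2 fold change −5.00 ± 0.27, adjusted p = 7.96e-10). The transcription factor gene Id4 fell from 50.6 ± 8.19 to 2.62 ± 0.602, Etv5 from 105 ± 10.3 to 3.70 ± 1.48 and Foxc2 from 139 ± 14.8 to 3.42 ± 1.59. The translational repressor gene Nanos2 went from 13.0 ± 2.90 to 0.225 ± 0.129 CPM. Zbtb16 (593 ± 39.2 to 115 ± 10.1), Lin28a (499 ± 35.9 to 147 ± 11.2) and Ccnd2 (321 ± 5.87 to 85.0 ± 6.93) fell less. On the log2 scale these fell by 2.37, 1.76 and 1.92 (adjusted p = 7.07e-06, 0.000139 and 2.67e-05). Kit, the stem cell factor receptor gene (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722), rose 34.1-fold, from 17.3 ± 1.24 to 589.8 ± 57.3 CPM (log2 fold change 5.09 ± 0.16, adjusted p = 1.09e-11).

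Other genes of differentiation rose with Kit. Tbx1 went from 4.35 ± 1.26 to 211 ± 18 CPM (48.4-fold) and Dmrtb1 from 12.4 ± 4.25 to 390.2 ± 46.4. With Kit and Pcsk1n (1.80 ± 0.714 to 51.5 ± 4.05) these are among the 5 largest rises. Stra8 rose from 49.5 ± 0.825 to 328 ± 38.2 CPM (log2 fold change 2.73 ± 0.31, adjusted p = 2.23e-06). The DNA methyltransferase gene Dnmt3b rose from 157 ± 11.9 to 294 ± 11.9 CPM (log2 fold change 0.90 ± 0.19, adjusted p = 0.000844). Sohlh1 stood at 130.3 ± 4.48 and 100.3 ± 4.60 CPM and did not pass (log2 fold change −0.38 ± 0.21, adjusted p = 0.159). For Sohlh1, Diff.Spg against Undiff.Spg, the test passed with only these 6 libraries fitted (adjusted p = 2.51e-05) and with DESeq2 (0.0494), and adjusted p reached 0.329 in other alternatives. Igfbp6 had the largest fall, 110-fold from 59.9 ± 5.21 to 0.541 ± 0.154 CPM. The cyclin-dependent kinase inhibitor gene Cdkn1b (84.2 ± 2.23 to 1.40 ± 0.430), Six4 (76.3 ± 7.06 to 1.42 ± 0.508) and Foxc2 came next. The ERK phosphatase gene Dusp6 (122 ± 11.9 to 3.01 ± 1.61) had the fifth largest fall. In all, 1763 genes were at least 2-fold higher and 2753 at least 2-fold lower in Diff.Spg, which answers how the spermatogonia under these 2 labels differ. Without the fold condition the counts were 3788 and 4273.

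Gene lists of stages and pathways were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the libraries. The undifferentiated spermatogonia list had a median log2 fold change of −3.54 (camera adjusted p = 2.01e-15, adjusted p = 0.0257 with an estimated correlation). Over all genes 27 of 28 were lower, and as many adjusted over the list alone. Ret, Nanos2, Foxc2 and Tspan8 (10.02 ± 1.44 to 0.297 ± 0.215 CPM) had its largest falls. This was the only list of the step whose call held with the estimated correlation. The mitotic cell cycle list had a median log2 fold change of 0.94 (camera adjusted p = 3.22e-08, adjusted p = 0.303 with an estimated correlation). Of its 22 tested genes, 18 were higher, over all genes and adjusted over the list alone. Plk1 rose from 40.5 ± 3.42 to 200 ± 17.9 CPM and Mki67 from 159 ± 34.1 to 553 ± 33.6. Tpx2 went from 73.0 ± 4.90 to 239.8 ± 10.6 and Aurka from 36.8 ± 0.796 to 96.7 ± 5.65. The DNA replication list had a median log2 fold change of 0.54 (camera adjusted p = 0.000284, adjusted p = 0.549 with an estimated correlation). Over all genes 21 of 30 were higher and 2 lower, with the same counts adjusted over the list alone. Rrm2 rose from 22.0 ± 2.11 to 83.8 ± 6.54 CPM, while the X-linked Pola1 fell from 29.7 ± 0.884 to 14.2 ± 0.846. The differentiating spermatogonia list had a median log2 fold change of 1.88 (camera adjusted p = 7.41e-05, adjusted p = 0.303 with an estimated correlation). Of its 13 tested genes, 10 were higher and 1 lower, over all genes and adjusted over the list alone. Kit, Dmrtb1 and Stra8 are among its rises and Ccnd2 is its fall. The meiotic entry list had a median log2 fold change of 0.95 (camera adjusted p = 0.000176, adjusted p = 0.163 with an estimated correlation). Of its 15 tested genes, 11 were higher and 1 lower over all genes, and 12 and 1 adjusted over the list alone. In it Prdm9 went from 1.31 ± 0.420 to 13.8 ± 1.32 CPM. Gm4969, the annotation's name for Meiosin, went from 3.40 ± 0.485 to 18.1 ± 6.35 and Meioc from 14.5 ± 1.97 to 66.4 ± 1.80.

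Other lists were called in the same step, with all libraries at the preset correlation only. The immediate early and heat shock list had a median log2 fold change of −1.72 (camera adjusted p = 2.02e-05, adjusted p = 0.0531 with an estimated correlation). Of its 16 tested genes, 11 were lower over all genes and 14 adjusted over the list alone. Its adjusted p with an estimated correlation was 0.0357 without PreL replicate 2 and LZ replicate 2. Such genes are also induced by the handling of cells. Egr1 fell from 411 ± 23.9 to 18.8 ± 1.96 CPM and Fos from 76.0 ± 6.36 to 8.05 ± 0.670. The piRNA list had a median log2 fold change of −0.45 (camera adjusted p = 0.00214, adjusted p = 0.312 with an estimated correlation). Of its 25 tested genes, 3 were higher and 15 lower over all genes, and 3 and 16 adjusted over the list alone. Spocd1 and Piwil4, which guide transposon methylation in fetal germ cells, fell from 61.4 ± 6.25 to 4.48 ± 0.433 and from 52.0 ± 3.95 to 9.45 ± 0.652 CPM. The retinoic acid list had a median log2 fold change of 0.46 (camera adjusted p = 0.0367, adjusted p = 0.221 with an estimated correlation). Of its 18 tested genes, 8 were higher and 2 lower over all genes, and 9 and 2 adjusted over the list alone. Cyp26b1, which encodes an enzyme that breaks retinoic acid down, rose from 2.04 ± 0.389 to 34.3 ± 2.41 CPM and Crabp1 from 76.2 ± 5.65 to 319.9 ± 13.0. Aldh1a3, for an enzyme that makes it, fell from 7.84 ± 1.57 to 0.420 ± 0.203. The ubiquitous glycolysis list had a median log2 fold change of −0.79 (camera adjusted p = 0.0268, adjusted p = 0.446 with an estimated correlation). Of its 16 tested genes, 1 was higher and 10 lower over all genes, and 2 and 10 adjusted over the list alone. The pyruvate kinase gene Pkm fell from 531 ± 39.6 to 105 ± 5.86 CPM. The ribosomal protein list had a median log2 fold change of −0.49 (camera adjusted p = 0.00775, adjusted p = 0.916 with an estimated correlation). Of its 51 tested genes, 1 was higher and 22 lower, over all genes and adjusted over the list alone. Rpl4 fell from 2291 ± 269.8 to 1171 ± 3.67 CPM, though reads of such genes may come from their many near-identical copies.

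**Figure D3:**
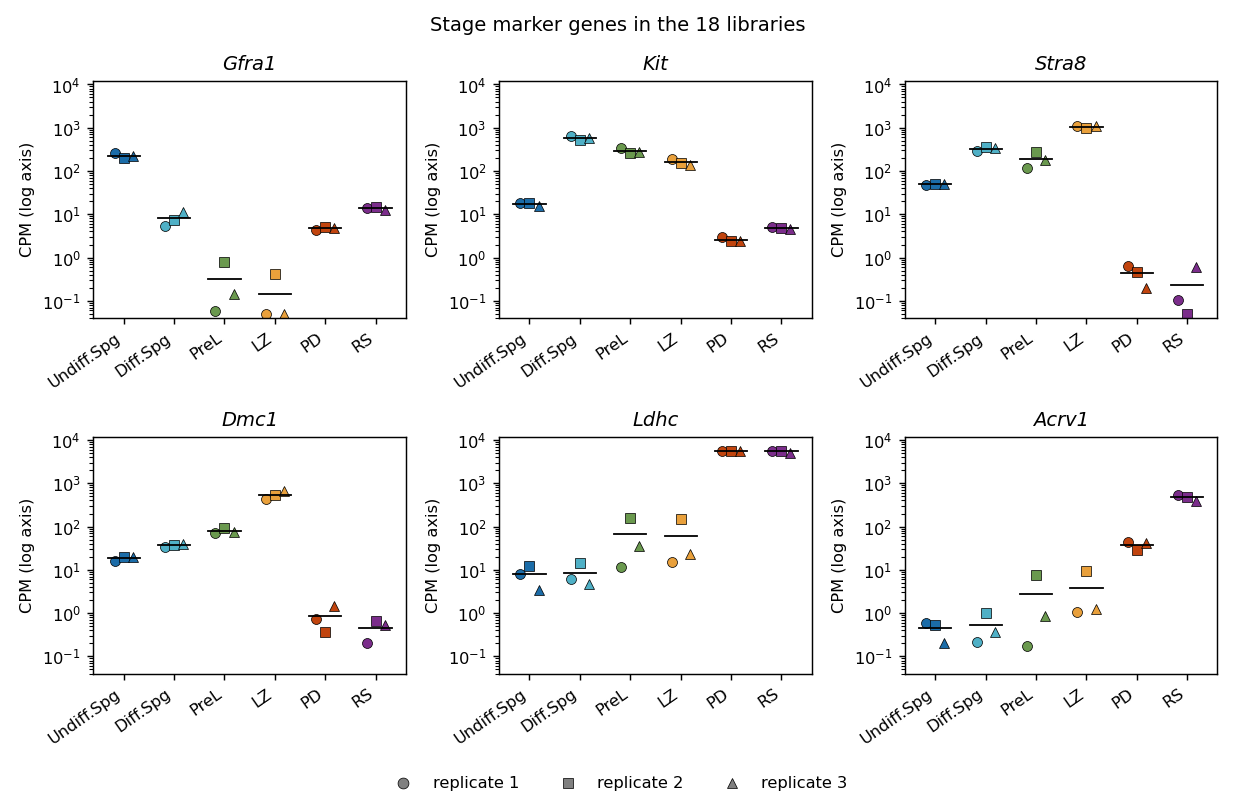
CPM (log axis) of Gfra1, Kit, Stra8, Dmc1, Ldhc and Acrv1 in the 6 groups (points, libraries; lines, group means). Gfra1 is highest in Undiff.Spg (228 CPM), Kit in Diff.Spg (589.8), Stra8 and Dmc1 in LZ (1054 and 538), Ldhc is abundant from PD on (5560 in PD), and Acrv1 is highest in RS (469.8).

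From Diff.Spg to PreL, genes such as Ccnd2 and Lin28a fall and genes such as Meioc and Rec8 rise. The cyclin gene Ccnd2 fell 167-fold, from 85.0 ± 6.93 to 0.498 ± 0.111 CPM (log2 fold change −7.38 ± 0.40, adjusted p = 1.69e-09). Lin28a fell from 147 ± 11.2 to 1.35 ± 0.416 (log2 fold change −6.74 ± 0.40, adjusted p = 3e-09). Meioc, needed to sustain the meiotic programme, rose from 66.4 ± 1.80 to 437 ± 50.7 CPM (log2 fold change 2.72 ± 0.13, adjusted p = 4.13e-10). Gm4969 (Meiosin) rose from 18.1 ± 6.35 to 129 ± 50.1 (log2 fold change 2.83 ± 0.34, adjusted p = 4.86e-06) and the meiotic cohesin gene Rec8 from 30.5 ± 5.40 to 100.3 ± 8.86 (log2 fold change 1.72 ± 0.16, adjusted p = 2.76e-07). Prdm9, which sets recombination sites, rose from 13.8 ± 1.32 to 57.6 ± 14.1 CPM, Sycp1 from 146 ± 12.3 to 376 ± 93.7 and the recombinase gene Dmc1 from 36.9 ± 2.75 to 80.0 ± 12.8. Their adjusted p-values were 2.51e-06, 2.04e-05 and 0.000608. Prss50 had the largest rise, 10.1-fold from 43.6 ± 10.2 to 442 ± 12.8 CPM (log2 fold change 3.34 ± 0.25, adjusted p = 2.94e-08).

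Kit fell from 589.8 ± 57.3 to 295 ± 45.2 CPM (log2 fold change −1.0 ± 0.14, adjusted p = 2.09e-05) and Dnmt3b from 294 ± 11.9 to 66.0 ± 12.4 (log2 fold change −2.15 ± 0.19, adjusted p = 2.34e-07). Dmrt1 stood at 813 ± 34.4 and 635 ± 137 CPM and did not pass (log2 fold change −0.36 ± 0.22, adjusted p = 0.205). Stra8 was lower in PreL, going from 328 ± 38.2 to 190.2 ± 75.3 CPM (log2 fold change −0.78 ± 0.29, adjusted p = 0.0364). That fall was −1.12 without PreL replicate 2 and −0.53 without PreL replicate 1 (adjusted p = 0.116). For Stra8, PreL against Diff.Spg, adjusted p lay between 9.08e-05 and 0.116 over the alternatives, and the fall was not called with RLE scaling (0.0564), with total library size (0.0538) or with these 6 libraries fitted alone (0.0744). Sycp3 rose from 45.5 ± 3.42 to 67.2 ± 15.1 CPM (log2 fold change 0.56 ± 0.17, adjusted p = 0.011), with 0.38 (adjusted p = 0.0666) without PreL replicate 3. After Ccnd2 and Lin28a the largest falls were those of Erg (54.9 ± 2.10 to 0.645 ± 0.510 CPM), Utrn (58.1 ± 2.10 to 0.901 ± 0.323) and Sh3d19 (51.8 ± 4.66 to 0.884 ± 0.474). For Erg the log2 change was −6.47, and −7.21 without PreL replicate 3. The other large rises depend on PreL replicate 2. Ldhc went from 8.36 ± 5.20 to 69.0 ± 80.2 CPM (log2 fold change 3.04 ± 0.88, adjusted p = 0.01), and without that library its change was 1.45 (adjusted p = 0.127). Fhl4 went from 7.47 ± 4.52 to 61.2 ± 70.1 (3.03 ± 0.71, and 1.47 without it). BC051142 went from 6.50 ± 3.78 to 52.1 ± 36.0 (2.99 ± 0.45, and 2.25 without it). Without Diff.Spg replicate 2 these log2 values were 3.68, 3.66 and 3.58. In all, 1706 genes were higher and 3056 lower in PreL, which answers what parts the Diff.Spg and PreL labels. Without PreL replicate 2 and LZ replicate 2 the counts were 1432 (1250 shared) and 3273 (2795 shared). Without the fold condition they were 3784 and 4596.

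The undifferentiated spermatogonia list had a median log2 fold change of −3.17 and of −3.06 with genes at 0 reads at their bound (camera adjusted p = 2.56e-11, adjusted p = 0.0486 with an estimated correlation). Of its 28 tested genes, 25 were lower over all genes and 26 adjusted over the list alone. This list alone kept its call in this step with the estimated correlation. The differentiating spermatogonia list was not called (3 of 13 higher and 8 lower, camera adjusted p = 0.132). The synaptonemal complex and cohesin list had a median log2 fold change of 0.80 (camera adjusted p = 2.22e-05, adjusted p = 0.0915 with an estimated correlation). Of its 13 tested genes, 11 were higher, over all genes and adjusted over the list alone. Rad21l (4.94 ± 1.03 to 16.4 ± 5.91 CPM), Rec8 and Sycp2 (58.3 ± 3.16 to 183 ± 43.0) were in front. The meiotic entry list had a median log2 fold change of 1.03 (camera adjusted p = 7.41e-05, adjusted p = 0.152 with an estimated correlation). Over all genes 10 of 15 were higher and 1 lower, with the same counts adjusted over the list alone. Meioc, Gm4969 and Prdm9 rose in it and Stra8 fell. The meiotic recombination list had a median log2 fold change of 0.52 (camera adjusted p = 0.000176, adjusted p = 0.275 with an estimated correlation). Of its 35 tested genes, 16 were higher and 1 lower, over all genes and adjusted over the list alone. Prdm9 is among its largest rises. The mitotic cell cycle list had a median log2 fold change of 0.40 (camera adjusted p = 0.00628, adjusted p = 0.684 with an estimated correlation). Over all genes 13 of 22 were higher and 1 lower, with the same counts adjusted over the list alone. Nusap1 rose from 73.8 ± 1.91 to 198 ± 38.0 CPM and Mki67 from 553 ± 33.6 to 1135 ± 396. The ubiquitous glycolysis list had a median log2 fold change of −0.81 (camera adjusted p = 0.00514, adjusted p = 0.303 with an estimated correlation). Of its 16 tested genes, 1 was higher and 9 lower, over all genes and adjusted over the list alone. The hexokinase gene Hk2 fell from 67.0 ± 5.97 to 3.83 ± 1.34 CPM and Aldoa from 148 ± 3.44 to 30.3 ± 6.09.

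The retinoic acid list had a median log2 fold change of −0.97 (camera adjusted p = 0.0192, adjusted p = 0.153 with an estimated correlation). Of its 18 tested genes, 4 were higher and 11 lower over all genes, and 4 and 12 adjusted over the list alone. The retinol dehydrogenase family gene Dhrs3 fell from 1.84 ± 0.288 to 0.178 ± 0.0439 CPM. The piRNA list had a median log2 fold change of −0.23 (camera adjusted p = 0.0195, adjusted p = 0.446 with an estimated correlation). Of its 25 tested genes, 2 were higher and 11 lower, over all genes and adjusted over the list alone. Henmt1 fell from 42.9 ± 0.740 to 12.7 ± 0.959 CPM, while Mybl1 rose from 1.76 ± 0.205 to 8.64 ± 3.18. The endothelial cell list had a median log2 fold change of −2.58 (camera adjusted p = 0.0123, adjusted p = 0.337 with an estimated correlation). Of its 8 tested genes, 5 were lower over all genes and 6 adjusted over the list alone. In it Cdh5 fell from 3.40 ± 0.467 to 0.0373 ± 0.0323 CPM. The nuclear oxidative phosphorylation list had a median log2 fold change of 0.21 (camera adjusted p = 0.0334, adjusted p = 0.919 with an estimated correlation). Of its 38 tested genes, 14 were higher and 1 lower over all genes, and 13 and 1 adjusted over the list alone. Ndufa1 rose from 24.1 ± 3.24 to 51.7 ± 15.7 CPM and Ndufa8 fell from 49.4 ± 1.92 to 27.1 ± 5.19.

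Lists of late genes were called higher in PreL as well, with fewer members called higher without PreL replicate 2 and LZ replicate 2. The pachytene list had a median log2 fold change of 1.33 (camera adjusted p = 0.00214, adjusted p = 0.684 with an estimated correlation). Of its 25 tested genes, 15 were higher and 1 lower over all genes, and 16 and 1 adjusted over the list alone. Without both libraries 11 were higher and 3 lower (camera adjusted p = 0.00394, adjusted p = 0.462 with an estimated correlation). The flagellum and axoneme list had a median log2 fold change of 2.15 (camera adjusted p = 0.00352, adjusted p = 0.89 with an estimated correlation). Of its 34 tested genes, 20 were higher and 1 lower over all genes, and 24 and 1 adjusted over the list alone. Without both, 10 were higher and 4 lower (0.158). The round spermatid list had a median log2 fold change of 2.07 (camera adjusted p = 0.0197, adjusted p = 0.916 with an estimated correlation). Over all genes 16 of 40 were higher, and as many adjusted over the list alone. Without both, 2 were higher and 6 lower (0.922). The testis glycolysis list had a median log2 fold change of 2.71 (camera adjusted p = 0.0435, adjusted p = 0.807 with an estimated correlation). Of its 10 tested genes, 8 were higher, over all genes and adjusted over the list alone. Without both, 4 were higher (0.173). Called higher only without both were the mitochondrially encoded list (7 of 7 higher, median 0.77, camera adjusted p = 0.00676), the DNA replication list (10 higher and 2 lower, 0.0115) and the ribosomal protein list (13 higher and 0 lower, 0.0301). None of the 3 was called with an estimated correlation (adjusted p = 0.578, 0.578 and 0.848). The log2 change of Rsph1 was 3.05 ± 0.73, and 1.85 without PreL replicate 2, and that of Spag6l 3.58 ± 0.89 and 2.20. Pgk2 went from 2.73 ± 0.88 to 0.85 without that library (adjusted p = 0.419) and Spaca7 from 3.36 ± 1.26 to −1.07 (0.61). Catsper1 went from 3.13 ± 1.12 to −0.08 (0.997) and Odf3 from 3.04 ± 1.05 to 0.17 (0.941).

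From PreL to LZ, genes of meiotic recombination such as Spo11 and Dmc1 rise. Spo11, which makes the double-strand breaks, rose from 4.09 ± 2.60 to 48.2 ± 7.13 CPM (log2 fold change 3.54 ± 0.29, adjusted p = 7.07e-08). Dmc1 rose from 80.0 ± 12.8 to 538 ± 106 (log2 fold change 2.75 ± 0.23, adjusted p = 9.85e-08) and the axis protein gene Hormad1 from 55.9 ± 12.5 to 256 ± 26.3 (log2 fold change 2.20 ± 0.17, adjusted p = 5.52e-08). The single-strand binding gene Meiob rose from 4.30 ± 2.61 to 113 ± 22.7 CPM (log2 fold change 4.70 ± 0.33, adjusted p = 2.02e-08) and Mei4, needed for the breaks, from 13.3 ± 2.14 to 27.5 ± 6.22 (log2 fold change 1.05 ± 0.19, adjusted p = 0.00035). Sycp1 and Sycp3, which build the synaptonemal complex, rose from 376 ± 93.7 to 958 ± 114 and from 67.2 ± 15.1 to 359 ± 68.5 CPM (adjusted p = 1.5e-05 and 2.39e-08). Stra8 (ENSMUSG00000029848, chromosome 6, 34920163 to 34939344) reached its highest level in LZ, from 190.2 ± 75.3 to 1054 ± 79.3 CPM (log2 fold change 2.47 ± 0.30, adjusted p = 4.5e-06). So did its partner Gm4969 (Meiosin), from 129 ± 50.1 to 825 ± 103 (log2 fold change 2.67 ± 0.33, adjusted p = 5.13e-06).

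Rad51ap2 had the largest rise, 36.6-fold from 2.73 ± 1.79 to 101 ± 24.4 CPM, followed by Fbxo47 (5.17 ± 3.44 to 137 ± 32.6). The class II MHC gene H2-Ab1 (3.40 ± 2.14 to 66.6 ± 22.5), the class I MHC gene H2-D1 (15.3 ± 7.29 to 291 ± 81.2) and the crossover helicase gene Hfm1 (24.8 ± 7.56 to 367 ± 53.7) came next. Without PreL replicate 2 the log2 rise was 5.89 for Rad51ap2 (5.19 ± 0.42 with it) and 5.38 for Fbxo47 (4.72 ± 0.38). It was 4.92 for H2-Ab1 (4.28 ± 0.52), 4.21 for Spo11 and 5.31 for Meiob. MHC genes have close paralogs, so reads may be shared among them. The mitotic kinase gene Aurkb had the largest fall, 27.2-fold from 109 ± 20.9 to 4.0 ± 0.697 CPM (log2 fold change −4.76 ± 0.20, adjusted p = 5.49e-10). Plk5 (80.8 ± 13.3 to 7.31 ± 0.851), Nutm1 (114 ± 25.1 to 12.2 ± 2.98), Dnmt3b (66.0 ± 12.4 to 7.73 ± 0.637) and Col5a1 (68.5 ± 14.7 to 8.49 ± 0.815) followed. Rec8 did not pass (100.3 ± 8.86 and 114 ± 16.6 CPM, log2 fold change 0.18 ± 0.15, adjusted p = 0.37), nor did Piwil2 (178 ± 15.8 and 193 ± 16.2, adjusted p = 0.659). The same held for Piwil1 (20.3 ± 15.7 and 16.6 ± 17.5, adjusted p = 0.746) and Ccna1 (6.42 ± 5.86 and 4.72 ± 5.83, adjusted p = 0.659). Mki67 fell from 1135 ± 396 to 759 ± 19.3 CPM (log2 fold change −0.58 ± 0.20, adjusted p = 0.0216), with −0.26 and adjusted p = 0.206 without PreL replicate 1. In all, 2717 genes were higher and 2428 lower in LZ, which answers what changes between the PreL and LZ labels. Without PreL replicate 2 and LZ replicate 2 they were 3005 (2470 shared) and 2698, and without the fold condition 4516 and 4302. With total library size in place of TMM scaling they were 2107 and 3174, as the median of all genes shifted by −0.20 on the log2 scale.

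The meiotic recombination list had a median log2 fold change of 1.84 (camera adjusted p = 4.33e-10, adjusted p = 0.0531 with an estimated correlation). Over all genes 29 of 35 were higher and 2 lower, with the same counts adjusted over the list alone. Dmc1, Hormad1 and Meiob are among its rises. The synaptonemal complex and cohesin list had a median log2 fold change of 1.63 (camera adjusted p = 7.31e-06, adjusted p = 0.0825 with an estimated correlation). Of its 13 tested genes, 11 were higher and 1 lower, over all genes and adjusted over the list alone. Rad21l rose from 16.4 ± 5.91 to 199.8 ± 33.6 CPM and Sycp2 from 183 ± 43.0 to 1060 ± 131. The meiotic entry list had a median log2 fold change of 1.62 (camera adjusted p = 3.31e-05, adjusted p = 0.134 with an estimated correlation). Over all genes 13 of 15 were higher and 1 lower, with the same counts adjusted over the list alone. Prdm9 rose from 57.6 ± 14.1 to 304 ± 48.6 CPM. The mitotic cell cycle list had a median log2 fold change of −1.11 (camera adjusted p = 3.24e-06, adjusted p = 0.393 with an estimated correlation). Of its 22 tested genes, 3 were higher and 17 lower, over all genes and adjusted over the list alone. Plk1 fell from 291 ± 70.0 to 38.9 ± 12.0 CPM and Cdk1 from 99.7 ± 26.9 to 18.2 ± 8.11, while the checkpoint kinase gene Bub1 rose from 188 ± 7.63 to 652 ± 84.7. The differentiating spermatogonia list had a median log2 fold change of −1.39 (camera adjusted p = 0.00447, adjusted p = 0.446 with an estimated correlation). Over all genes 2 of 13 were higher and 9 lower, with the same counts adjusted over the list alone. Dmrtb1 fell from 650.4 ± 147 to 96.5 ± 30.4 CPM and Dmrt1 from 635 ± 137 to 202 ± 29.0.

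The ribosomal protein list had a median log2 fold change of −0.37 (camera adjusted p = 0.00667, adjusted p = 0.916 with an estimated correlation). Of its 51 tested genes, 1 was higher and 21 lower, over all genes and adjusted over the list alone. Rps3 fell from 452 ± 241 to 182 ± 47.8 CPM and Rps20 rose from 150.2 ± 55.4 to 266 ± 41.5. The proteasome list had a median log2 fold change of −0.45 (camera adjusted p = 0.0234, adjusted p = 0.76 with an estimated correlation). Over all genes 10 of 17 were lower, and as many adjusted over the list alone. Psmb3 fell from 52.3 ± 24.9 to 13.7 ± 3.15 CPM and Psma7 from 138 ± 52.4 to 45.7 ± 13.9. The Sertoli cell list had a median log2 fold change of 1.55 (camera adjusted p = 0.0102, adjusted p = 0.501 with an estimated correlation). Of its 15 tested genes, 10 were higher and 1 lower, over all genes and adjusted over the list alone. In LZ Amhr2 stood at 11.2 ± 2.46 CPM and Clu at 55.8 ± 16.8, against 13.3 for Clu in PreL. Without PreL replicate 2 and LZ replicate 2 the Sertoli counts were 8 and 1 (camera adjusted p = 0.0216, adjusted p = 0.506 with an estimated correlation). The testis histone list had a median log2 fold change of 1.91 (camera adjusted p = 0.0295, adjusted p = 0.612 with an estimated correlation). Over all genes 4 of 12 were higher, and as many adjusted over the list alone. Hist1h2ba rose from 1.61 ± 0.906 to 10.4 ± 2.31 CPM, and without both libraries 10 members were higher (0.00394, and 0.382 with an estimated correlation). LZ replicate 1, which stays in that fit, stood apart for Prm1 (22.7 CPM, 4.23 and 2.72 in the others) and Prm2 (32.1 CPM, 3.03 and 3.82 in the others). The round spermatid list was not called (camera adjusted p = 0.333), but without both libraries 20 members were higher and 1 lower (0.00449, and 0.736 with an estimated correlation). The autosomal retrocopy list was called only without both as well (0.0493, and 0.51 with an estimated correlation).

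From LZ to PD, most of the transcriptome changes, and genes such as Stra8 and Dmc1 fall while genes such as Ldhc and Piwil1 rise. Stra8 fell from 1054 ± 79.3 to 0.430 ± 0.224 CPM (log2 fold change −11.21 ± 0.48, adjusted p = 1.63e-12), Prdm9 from 304 ± 48.6 to 0.526 ± 0.342 (log2 fold change −9.14 ± 0.35, adjusted p = 4.45e-13) and Dmc1 from 538 ± 106 to 0.854 ± 0.560 (log2 fold change −9.30 ± 0.34, adjusted p = 2.61e-13). The testis lactate dehydrogenase gene Ldhc (ENSMUSG00000030851, chromosome 7, 46861203 to 46878142) rose from 62.0 ± 74.5 to 5560 ± 116 CPM (log2 fold change 6.48 ± 1.02, adjusted p = 1.63e-05). The piRNA-binding protein gene Piwil1 rose from 16.6 ± 17.5 to 1992 ± 421 (log2 fold change 6.91 ± 0.75, adjusted p = 2.11e-07) and the meiotic cyclin gene Ccna1 from 4.72 ± 5.83 to 359.8 ± 69.4 (log2 fold change 6.24 ± 0.78, adjusted p = 1.28e-06). Hspa2, a testis chaperone gene, rose from 214 ± 62.2 to 3492 ± 205 CPM (log2 fold change 4.03 ± 0.26, adjusted p = 1.96e-10) and the testis proteasome gene Psma8 from 13.1 ± 5.11 to 257 ± 36.8 (log2 fold change 4.29 ± 0.23, adjusted p = 2.32e-11).

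The retrogene Pgk2 rose from 8.31 ± 8.42 to 358 ± 45.2 CPM (log2 fold change 5.42 ± 0.84, adjusted p = 1.55e-05) and the acrosin gene Acr from 8.26 ± 10.1 to 394 ± 13.3 (log2 fold change 5.57 ± 0.87, adjusted p = 1.68e-05). Spo11, which has a later testis isoform, rose from 48.2 ± 7.13 to 124 ± 3.20 (log2 fold change 1.36 ± 0.25, adjusted p = 9.56e-05). Without LZ replicate 2, which holds the most late transcripts of its group, the log2 rise was 8.18 for Ldhc, 8.25 for Piwil1 and 7.98 for Ccna1. It was 6.69 for Pgk2 and 7.29 for Acr. Without LZ replicate 3 the log2 rise of Piwil1 was 6.27. Without PD replicate 1 the change of Prdm9 was −9.97, and without PD replicate 3 that of Dmc1 was −10.10. Mybl1, a master regulator of pachytene genes, rose from 114 ± 13.4 to 173 ± 7.04 CPM (log2 fold change 0.60 ± 0.20, adjusted p = 0.0115). For Mybl1, PD against LZ, the rise did not pass without PD replicate 3 (0.37, adjusted p = 0.149) or with total library size (0.20, adjusted p = 0.44), and adjusted p was as low as 0.00111 in other alternatives. Hist1h1t, the testis linker histone gene, stood at 1.89 ± 1.16 and 2.24 ± 0.281 CPM and did not pass (log2 fold change 0.24 ± 0.52, adjusted p = 0.683). Kif4-ps (0.452 ± 0.596 to 100.2 ± 6.00 CPM, 7.73 ± 0.50) and Crtam (0.691 ± 0.698 to 137 ± 49.3, 7.58 ± 0.62) had the largest rises. H2afy3 (0.262 ± 0.263 to 52.8 ± 6.00, 7.57 ± 0.46), Daw1 (0.333 ± 0.450 to 65.9 ± 1.86, 7.56 ± 0.54) and Pou5f2 (1.35 ± 1.77 to 242 ± 19.5, 7.45 ± 0.68) came next. Without LZ replicate 2 these 5 log2 values were 9.68, 8.79, 8.76, 9.61 and 9.45. Without LZ replicate 3 they were 6.97 for Kif4-ps and 6.80 for Daw1.

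Among the largest falls, the X-linked chloride channel gene Clcn5 (ENSMUSG00000004317, chromosome X, 7153810 to 7319358) stood at 80.6 ± 4.94 CPM in LZ and had no read in any PD library. It was at least 865-fold lower against a floor of 3 reads over the group. Tcn2 (61.8 ± 2.4 CPM in LZ) was at least 663-fold lower and the X-linked Tmem28 (56.6 ± 11.5) at least 609-fold lower. Rad21l had 1 read over the PD libraries against 199.8 ± 33.6 CPM in LZ, and the X-linked Hprt 2 reads against 169.9 ± 31.5 CPM. Pgk1, the X-linked parent of Pgk2, had 1 read in PD against 2.57 ± 0.318 CPM in LZ (adjusted p = 9.73e-08), and it has pseudogenes that may share its reads. In all, 6832 genes were higher and 6495 lower in PD, which answers what parts the LZ and PD labels. Without PreL replicate 2 and LZ replicate 2 the counts were 6951 and 6604. Without the fold condition they were 7807 and 7566. The median of all genes shifted by −0.35 with total library size and by 0.10 with RLE scaling.

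The flagellum and axoneme list had a median log2 fold change of 5.72 (camera adjusted p = 5.07e-07, adjusted p = 0.684 with an estimated correlation). Of its 34 tested genes, 34 were higher, over all genes and adjusted over the list alone. Odf2, of the sperm outer dense fibres, rose from 130.5 ± 51.3 to 3194 ± 215 CPM (log2 fold change 4.61 ± 0.22, adjusted p = 5.14e-12). The radial spoke gene Rsph1 rose from 33.5 ± 35.1 to 3068 ± 137 (6.52 ± 0.83, 7.83 without LZ replicate 2 and 5.86 without LZ replicate 3). The pachytene list had a median log2 fold change of 4.34 (camera adjusted p = 6.58e-06, adjusted p = 0.446 with an estimated correlation). Over all genes 24 of 25 were higher, and as many adjusted over the list alone. The round spermatid list had a median log2 fold change of 3.56 (camera adjusted p = 3.31e-05, adjusted p = 0.71 with an estimated correlation). Of its 40 tested genes, 40 were higher, over all genes and adjusted over the list alone. From PD to RS the same list rose by a further median of 3.13. RS transcripts stood in PD as given above, and how much of the round spermatid rise is RNA of RS cells was not tested. The testis glycolysis list had a median log2 fold change of 5.04 (camera adjusted p = 0.00948, adjusted p = 0.703 with an estimated correlation). Over all genes 10 of 10 were higher, and as many adjusted over the list alone. Ldhc and Pgk2 are among its members. The piRNA list had a median log2 fold change of 1.74 (camera adjusted p = 0.0239, adjusted p = 0.468 with an estimated correlation). Of its 25 tested genes, 17 were higher and 6 lower, over all genes and adjusted over the list alone. Tdrd5 rose from 10.1 ± 5.11 to 424 ± 73.1 CPM (log2 fold change 5.38 ± 0.37, adjusted p = 5.3e-10), while Fkbp6 fell from 385 ± 22.3 to 46.9 ± 10.6. The autosomal retrocopy list had a median log2 fold change of 3.03 (camera adjusted p = 0.0295, adjusted p = 0.463 with an estimated correlation). Over all genes 8 of 10 were higher and 1 lower, with the same counts adjusted over the list alone. Pdha2 rose from 25.5 ± 4.26 to 409 ± 28.9 CPM and Utp14b fell from 62.5 ± 5.19 to 43.0 ± 13.9.

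The DNA replication list had a median log2 fold change of −3.52 (camera adjusted p = 2.02e-05, adjusted p = 0.446 with an estimated correlation). Of its 30 tested genes, 2 were higher and 26 lower, over all genes and adjusted over the list alone. Mcm5 fell from 698 ± 128 to 10.4 ± 2.08 CPM (log2 fold change −6.06 ± 0.23, adjusted p = 3.3e-13) and Mcm7 rose from 113 ± 7.40 to 236 ± 9.80. The meiotic entry list had a median log2 fold change of −5.13 (camera adjusted p = 0.000159, adjusted p = 0.163 with an estimated correlation). Over all genes 1 of 15 was higher and 14 lower, with the same counts adjusted over the list alone. Stra8 and Prdm9 are among its falls. The meiotic recombination list had a median log2 fold change of −2.65 (camera adjusted p = 0.000162, adjusted p = 0.275 with an estimated correlation). Of its 35 tested genes, 6 were higher and 28 lower, over all genes and adjusted over the list alone. Cntd1 (25.4 ± 3.71 to 140 ± 9.28 CPM) is among its rises. The synaptonemal complex and cohesin list had a median log2 fold change of −2.4 (camera adjusted p = 0.0192, adjusted p = 0.393 with an estimated correlation). Over all genes 2 of 13 were higher and 11 lower, with the same counts adjusted over the list alone. Syce2 fell from 610.4 ± 134 to 29.2 ± 5.64 CPM and Syce1 rose from 357 ± 39.9 to 759 ± 17.0. The differentiating spermatogonia list had a median log2 fold change of −5.93 (camera adjusted p = 0.00817, adjusted p = 0.499 with an estimated correlation). Of its 13 tested genes, 2 were higher and 10 lower, over all genes and adjusted over the list alone. Dmrtb1 is among its rises, from 96.5 ± 30.4 to 1737 ± 110.3 CPM. The Sertoli cell list had a median log2 fold change of −4.75 and of −4.34 with genes at 0 reads at their bound (camera adjusted p = 0.00362, adjusted p = 0.446 with an estimated correlation). Over all genes 12 of 15 were lower, and as many adjusted over the list alone. Gata4 was at least 22.3-fold lower. The mitochondrially encoded list had a median log2 fold change of −3.04 (camera adjusted p = 0.0192, adjusted p = 0.703 with an estimated correlation). Of its 7 tested genes, 7 were lower, over all genes and adjusted over the list alone. The cytochrome b gene mt-Cytb fell from 13910 ± 3120 to 1690 ± 209 CPM (log2 fold change −3.04 ± 0.27, adjusted p = 2.02e-08). The ribosomal protein list had a median log2 fold change of −0.72 (camera adjusted p = 0.0435, adjusted p = 0.931 with an estimated correlation). Of its 51 tested genes, 5 were higher and 31 lower over all genes, and 4 and 30 adjusted over the list alone. Rps19 fell from 111 ± 19.6 to 20 ± 1.33 CPM and Rpl30 rose from 23.0 ± 2.35 to 62.1 ± 2.18.

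From PD to RS, genes such as Acrv1, Spaca1 and Catsper3 rise, and genes such as Sycp3 and Piwil1 fall. Acrv1, an acrosomal protein gene (ENSMUSG00000032110, chromosome 9, 36693220 to 36698843), rose 12.4-fold, from 37.9 ± 7.38 to 469.8 ± 84.3 CPM (log2 fold change 3.63 ± 0.75, adjusted p = 0.000481). Spaca1 rose from 36.5 ± 8.35 to 465 ± 98.5 (log2 fold change 3.67 ± 0.47, adjusted p = 4.29e-06) and Catsper3, of the sperm calcium channel, from 12.2 ± 1.63 to 158 ± 29.2 (log2 fold change 3.69 ± 0.47, adjusted p = 3.49e-06). Crem, for a transcription factor of spermatid genes, rose from 221 ± 10.1 to 558 ± 74.8 CPM (log2 fold change 1.34 ± 0.26, adjusted p = 0.000299) and Tssk6 from 12.5 ± 2.82 to 49.4 ± 4.96 (log2 fold change 1.98 ± 0.32, adjusted p = 3.76e-05). The transition protein gene Tnp1 rose from 44.9 ± 9.10 to 162 ± 27.7 (log2 fold change 1.85 ± 0.54, adjusted p = 0.00687). Sycp3 fell from 138 ± 11.8 to 30.2 ± 4.50 CPM (log2 fold change −2.20 ± 0.17, adjusted p = 1.45e-08), Sycp1 from 164 ± 36.6 to 87.5 ± 11.1 (log2 fold change −0.91 ± 0.19, adjusted p = 0.000441) and Piwil1 from 1992 ± 421 to 115 ± 59.0 (log2 fold change −4.11 ± 0.66, adjusted p = 3.82e-05). The synaptonemal complex and cohesin list as a whole was not called (4 of 13 higher and 6 lower, camera adjusted p = 0.594), nor was the pachytene list (3 of 25 higher and 6 lower, camera adjusted p = 0.733).

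Of the 12 tested testis histone and transition protein genes 6 were higher, 2 lower and 4 did not pass (camera adjusted p = 0.248 for the list). Of these 4, Tnp2 stood at 136 ± 29.6 and 379.9 ± 110.5 CPM (log2 fold change 1.48 ± 0.64, adjusted p = 0.0555) and Prm1 at 76.2 ± 19.1 and 203 ± 60.7 (adjusted p = 0.0916). Prm2 stood at 96.7 ± 24.3 and 239 ± 85.2 (adjusted p = 0.189) and Hist1h1t at 2.24 ± 0.281 and 3.54 ± 0.477 (adjusted p = 0.297). With only the PD and RS libraries fitted, the rise passed for Tnp2 (adjusted p = 0.000141), for Prm2 (0.00126) and for Prm1, RS against PD (0.000331). Over the alternatives adjusted p reached 0.166 for Tnp2, RS against PD, 0.242 for Prm1 and 0.382 for Prm2, RS against PD. Ccna1 stood at 359.8 ± 69.4 and 437 ± 14.4 CPM (adjusted p = 0.731). BC061237 had the largest rise, 20-fold from 2.82 ± 0.834 to 56.6 ± 7.68 CPM, then the X-linked Map7d3 (4.59 ± 1.38 to 78.1 ± 17.6). Mroh9 (11.03 ± 2.08 to 186 ± 27.9), the X-linked Alg13 (8.76 ± 0.554 to 144 ± 7.79) and Adam26a (6.10 ± 1.64 to 99.0 ± 20.8) followed. Beside these rises, 2 of the 6634 genes at 20 CPM or more in RS lay under 5% of their RS level in PD (lowest 4.54%). In the same way 17 of 6712 genes of PD lay under 5% of their PD level in RS (lowest 2.21%) and 3 of 6866 genes of LZ under 5% in PreL (lowest 2.7%). Under 5% also lay 906 genes of LZ in PD and 1041 genes of PD in LZ. The 5 largest falls were those of Pou5f2 (242 ± 19.5 to 6.61 ± 2.75 CPM), Ckap2 (61.4 ± 7.93 to 2.09 ± 1.48), Skap2 (61.4 ± 14.6 to 2.53 ± 1.42), Tex101 (257 ± 72.2 to 11.1 ± 7.27) and Sap30 (84.4 ± 5.05 to 3.85 ± 1.92). Without RS replicate 3 the log2 change was −5.69 for Ckap2 (−4.82 ± 0.30 with it), −5.21 for Skap2 (−4.56 ± 0.27) and −5.27 for Tex101 (−4.52 ± 0.34). In all, 4548 genes were higher and 3662 lower in RS, which answers what parts the PD and RS labels. Without the fold condition the counts were 5615 and 5301. The median of all genes shifted by −0.14 with total library size and by 0.14 with RLE scaling.

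The round spermatid list had a median log2 fold change of 3.13 (camera adjusted p = 2.07e-05, adjusted p = 0.703 with an estimated correlation). Of its 40 tested genes, 36 were higher over all genes and 37 adjusted over the list alone. Lyzl6 rose from 17.5 ± 3.66 to 224 ± 38.7 CPM and Spaca7 from 13.8 ± 2.87 to 174 ± 34.1, with the limit given above for Acrv1. The piRNA list had a median log2 fold change of −1.41 and of −1.23 with genes at 0 reads at their bound (camera adjusted p = 0.00719, adjusted p = 0.393 with an estimated correlation). Over all genes 5 of 25 were higher and 15 lower, with the same counts adjusted over the list alone. Tdrd1 fell from 600.1 ± 162 to 59.5 ± 16.7 CPM (log2 fold change −3.33 ± 0.23, adjusted p = 2.77e-09) and Tdrd5 from 424 ± 73.1 to 26.0 ± 10.9, while Gtsf1 rose from 256 ± 8.82 to 497 ± 50.7. The meiotic recombination list had a median log2 fold change of −0.85, −0.72 at the bounds (camera adjusted p = 0.0283, adjusted p = 0.549 with an estimated correlation). Of its 35 tested genes, 5 were higher and 16 lower over all genes, and 5 and 17 adjusted over the list alone. Mlh3 fell from 123 ± 9.57 to 18.3 ± 7.02 CPM and Tex15 rose from 17.4 ± 4.30 to 261 ± 55.7. The DNA replication list had a median log2 fold change of −0.78 (camera adjusted p = 0.0201, adjusted p = 0.732 with an estimated correlation). Over all genes 6 of 30 were higher and 17 lower, with the same counts adjusted over the list alone. Mcm3 fell from 12.1 ± 3.60 to 0.788 ± 0.0682 CPM and Rrm2 rose from 16.7 ± 3.95 to 39.9 ± 1.06. The nuclear oxidative phosphorylation list had a median log2 fold change of −0.29 (camera adjusted p = 0.0295, adjusted p = 0.916 with an estimated correlation). Of its 38 tested genes, 1 was higher and 17 lower over all genes, and 1 and 16 adjusted over the list alone. Sdhc fell from 122 ± 14.6 to 33.3 ± 3.66 CPM. The mitochondrially encoded list had a median log2 fold change of −1.48 (camera adjusted p = 0.0192, adjusted p = 0.703 with an estimated correlation). Over all genes 7 of 7 were lower, and as many adjusted over the list alone. Here mt-Cytb fell from 1690 ± 209 to 495 ± 75.4 CPM.

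The sex chromosomes, which are known to be silenced in pachytene cells, are all but silent in PD and come back in part in RS. The X-linked transcription factor gene Zfx fell from 98.6 ± 8.28 to 0.439 ± 0.128 CPM between LZ and PD (log2 fold change −7.79 ± 0.20, adjusted p = 1.33e-14) and rose to 7.33 ± 0.656 in RS (log2 fold change 4.04 ± 0.21, adjusted p = 2.38e-10). X-linked genes took 2.44 ± 0.012% of counted reads in Undiff.Spg, 2.35 ± 0.0186% in Diff.Spg, 2.64 ± 0.0852% in PreL and 2.81 ± 0.114% in LZ. They took 0.0707 ± 0.0126% in PD and 0.651 ± 0.0772% in RS. The Y-linked Usp9y fell from 62.8 ± 17.4 to 0.964 ± 0.135 CPM between LZ and PD (log2 fold change −6.01 ± 0.22, adjusted p = 3.25e-13) and rose to 16.2 ± 0.759 in RS. Y-linked Eif2s3y rose from 7.49 ± 2.16 to 104 ± 27.3 CPM between PD and RS (log2 fold change 3.79 ± 0.24, adjusted p = 1.22e-09). Y-linked genes took 0.047 ± 0.00913% of reads in LZ, 0.00253 ± 0.000771% in PD and 0.0296 ± 0.00952% in RS.

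Of 750 tested X-linked genes, 537 were at least 2-fold lower in PD than in LZ and 141 higher. Their median log2 fold change less that of 17658 autosomal genes was −5.72 (camera adjusted p = 6.82e-15, adjusted p = 0.00396 with an estimated correlation). The X-linked median itself was −5.63, and −4.72 with genes at 0 reads at their bound. Of 214 X-linked genes at 20 CPM or more in LZ, 147 (68.7%) lay under 1% of their LZ level in PD and 0 above that level. Their medians were 0.399% in PD and 3.45% in RS. Of 6635 such autosomal genes, 233 (3.51%) lay under 1%, with medians of 59.4% and 44%. Between PD and RS, 455 X-linked genes were higher and 2 lower (camera adjusted p = 1.94e-20, adjusted p = 0.002 with an estimated correlation). The median of the 750 was 3.07 above the autosomal one. The X-linked median itself was 3.33 with genes at 0 reads at their bound, leaving out 200 genes at or under it in both groups. X-linked genes above 1 CPM numbered 488 in LZ, 173 in PD and 388 in RS. The X-linked RNA counted in PD includes the RS transcripts described above.

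Earlier steps moved the X chromosome little. The X-linked Esx1 rose from 16.0 ± 3.10 to 203 ± 28.8 CPM between Undiff.Spg and Diff.Spg, but the X-linked median differed from the autosomal one by −0.06 (camera adjusted p = 0.415). It was 0.34 higher between Diff.Spg and PreL (adjusted p = 0.0225, adjusted p = 0.381 with an estimated correlation), and 0.06 higher without PreL replicate 2. Between PreL and LZ it was 0.08 higher (adjusted p = 0.361). The X-linked parent list had a median log2 fold change of −6.54 from LZ to PD, −6.64 at the bounds (camera adjusted p = 7.41e-05, adjusted p = 0.0531 with an estimated correlation). Of its 10 tested genes, 10 were lower, over all genes and adjusted over the list alone. The X-linked parent list had a median log2 fold change of 3.58 from PD to RS, 3.59 at the bounds (camera adjusted p = 0.000738, adjusted p = 0.0913 with an estimated correlation). Over all genes 8 of 10 were higher, and as many adjusted over the list alone. The Y-linked list had a median log2 fold change of −5.10 from LZ to PD (camera adjusted p = 0.00214, adjusted p = 0.446 with an estimated correlation). Of its 8 tested genes, 8 were lower, over all genes and adjusted over the list alone. The Y-linked list had a median log2 fold change of 3.68 from PD to RS (camera adjusted p = 0.00023, adjusted p = 0.38 with an estimated correlation). Over all genes 7 of 8 were higher, and as many adjusted over the list alone. Over the whole Y chromosome 29 of 32 tested genes were higher in RS than in PD. Their median log2 fold change was 3.75, or 3.79 at the bounds (camera adjusted p = 1.92e-12, adjusted p = 0.0487 with an estimated correlation). Between LZ and PD 12 were higher and 11 lower (median 2.07, 1.35 at the bounds, adjusted p = 0.914).

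**Figure D4:**
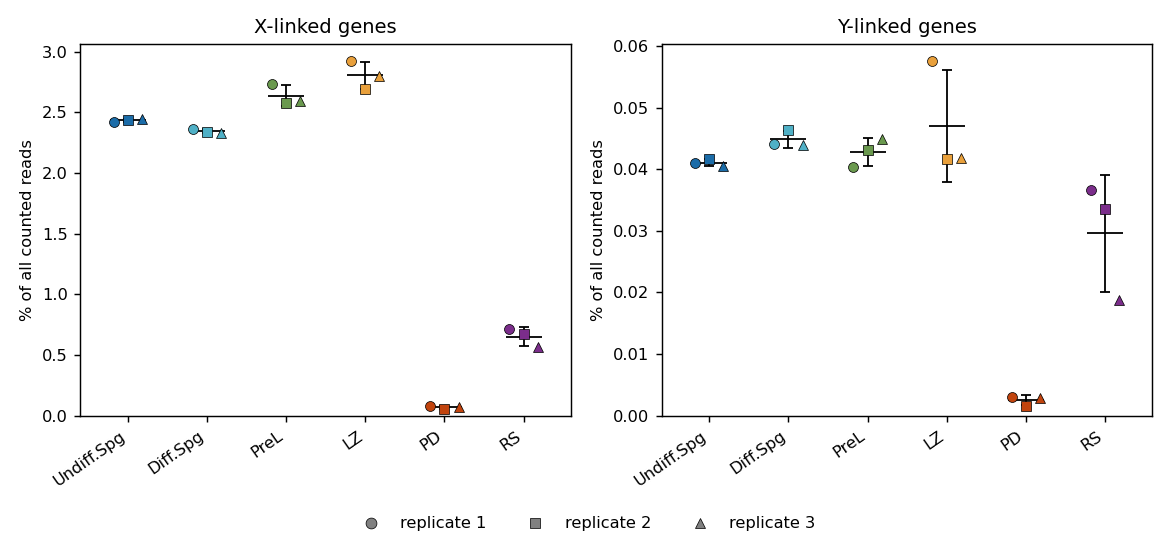
Share of counted reads (%) on the X and Y chromosomes in the 6 groups (points, libraries; lines, means; bars, SD; n = 3). The X share is 2.81% in LZ, 0.0707% in PD and 0.651% in RS.

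Some lists passed in no step. Over the 5 steps in order, camera adjusted p was 0.611, 0.824, 0.236, 0.0633 and 0.968 for the DNA methylation enzymes. Of the 10 tested, 6 were higher and 3 lower in Diff.Spg than Undiff.Spg. From LZ to PD 2 were higher and 8 lower (median log2 fold change −3.33). Camera adjusted p was 0.0773, 0.999, 0.834, 0.881 and 0.965 for the 3 immune genes expressed enough to test. It was 0.746, 0.702, 0.374, 0.437 and 0.808 for the 4 Leydig cell genes, and 0.916, 0.733, 0.327, 0.236 and 0.343 for the 10 genes of peritubular myoid cells and stroma. Summed over its genes, the immune list stood at 32.4 CPM in Undiff.Spg replicate 1 and at 5.3 and 6.75 in the other Undiff.Spg libraries. Summed over 16 genes without Dmrt1, the Sertoli list stood at 130, 91.1 and 70.8 CPM in LZ and at 26.1, 23.5 and 28.8 in PreL. Dmrt1, which also stands in the differentiating spermatogonia list, was left out of all Sertoli sums given here. Its own level, given above, exceeded these sums and fell between PreL and LZ. In Undiff.Spg and Diff.Spg the Sertoli list stood at 60.7, 55.3 and 60 CPM and at 35.1, 36.5 and 36.8, and the endothelial list at 42.3, 41.7 and 50.4 and at 28.3, 29.6 and 31.2. The myoid and stroma list stood at 99.6, 141 and 151 CPM in Undiff.Spg and at 38.5, 41.6 and 44.2 in Diff.Spg. It stood at 241, 239 and 201 CPM in RS and at 33.5, 27.8 and 31.8 in PD. Of 7 erythroid genes, 1 was expressed enough to test, so that list has no test. When the 6 libraries of a step were split in other ways, up to 14, 15, 16, 14 and 11 lists were called over the 5 steps at the preset correlation, against 10, 14, 9, 16 and 8 for the real groups.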

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

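Beside the chosen processing, 29 alternatives were run, among them each of the 18 libraries left out in turn. Over the 27 results of the comparisons, 687 values were kept and 19 changed. A count was taken as kept within 1.5 times the reported one, and a tested value when its direction and its side of adjusted p = 0.05 stayed, whatever its size. Of 346 gene-and-step results 299 kept their call in every alternative, and 47 changed in at least 1. DESeq2 changed none of the 17 comparison results it covers. Where a value changed, the cause was not tested.

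Without the fold condition the counts were, over the first 3 steps, 3788 higher and 4273 lower, 3784 and 4596, and 4516 and 4302, and the enriched genes numbered 554 in Diff.Spg, 343 in PreL, 1750 in LZ and 1510 in PD. With the estimated correlation 1, 1, 0, 0 and 0 lists were called over the 5 steps, and the X-linked difference between PreL and Diff.Spg stayed 0.34 with adjusted p = 0.381. Without a low-count filter that difference was 0 (adjusted p = 0.136). With total library size the log2 change between PreL and LZ was −0.025 for Rec8 and −0.094 for Piwil2, against positive values otherwise. That of Hist1h1t between LZ and PD was −0.145, against 0.24 with TMM scaling.

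Leaving out 1 library gave 35 to 79 PreL-enriched genes, 1256 to 2120 genes higher in PreL than Diff.Spg, an X-linked difference between PreL and Diff.Spg down to 0.06 (0.062), and an X-linked difference between LZ and PreL of −0.006 to 0.13. It moved the log2 change of Spaca7 between Diff.Spg and PreL over −1.07 to 3.96, of Catsper1 over −0.081 to 4.13, of Piwil1 between PreL and LZ over −1.65 to 0.55, of Ccna1 over −2.19 to 0.64, and of Hist1h1t between LZ and PD over −0.14 to 0.58. Without PreL replicate 2 and LZ replicate 2 together, Spaca7 was at −1.07 and Catsper1 at −0.086.

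With replicate number as a block, which the pairing of numbers between Diff.Spg, PreL and LZ calls for, genes higher in PreL than Diff.Spg numbered 1661 and genes lower in PreL than Diff.Spg 3041. The genes higher in LZ than PreL numbered 2688, the genes lower in LZ than PreL 2409, and 49 were enriched in PreL. The block ended the calls of Prr19, PreL against Diff.Spg (−0.28, adjusted p = 0.0556) and Spaca7, PreL against Diff.Spg (3.17, adjusted p = 0.0505), and moved each comparison count by less than 1.5 times.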

Other observations

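In this part, the tests of the 3 patterns below were chosen only after the results were seen. The rule for reading the splits of the samples, a share under 0.05, was written then as well. The class I MHC genes H2-K1 and H2-D1 stand highest in LZ. H2-K1 went from 135 ± 21.1 to 933 ± 196 CPM between PreL and LZ (log2 fold change 2.79, adjusted p = 8.96e-09, higher in 3 of 3 LZ libraries) and B2m, the light chain of class I, from 4.02 ± 0.233 to 29.6 ± 2.68 (2.88 ± 0.19, adjusted p = 1.24e-08). H2-D1 stood at 291 ± 81.2 CPM in LZ and at most at 15.3 in the other groups, but B2m stood at 28.1 ± 5.42 in Undiff.Spg as well. Beside the class II gene H2-Ab1, H2-Aa stood at 0.126 and Cd74 at 0.0470 CPM in LZ, and the leukocyte gene Ptprc at 0.0235. Of the genes that load class I, Tap1 stood at 0.444 CPM and Tapbp at 16.3 in LZ, against 0.254 and 8.59 in PreL and 2.75 and 193 in Undiff.Spg. Between PreL and LZ the log2 fold change was 0.92 ± 0.13 for Tapbp (adjusted p = 1.26e-05) and 0.75 ± 0.56 for Tap1 (adjusted p = 0.305). Id4, a gene of Undiff.Spg (50.6 CPM), stood at 113 ± 19.4 CPM in PD against 2.57 in LZ and 11.7 in RS. These genes were chosen after the values were seen.

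Late germ-cell transcripts stand higher in PreL replicate 2 (3.30%, as above) and LZ replicate 2 (3.25%) than in the other libraries of their groups. A scaling error is argued against, since genes absent from PD and RS stood at a ratio of 0.801 in PreL replicate 2 and 0.991 in LZ replicate 2 to the other libraries, not several times higher. Reads of the whole pool under a wrong index are argued against by genes of Undiff.Spg, which stood at 0.242% of their Undiff.Spg level. RNA of later germ cells at 1 share for all genes is a candidate explanation, as the interquartile range of the percentages was at most 0.262 of their median. Which later cells, and whether reads of PD and RS libraries alone took a wrong index, stays open, and no biological explanation was tested.

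Stra8 and Gm4969 (Meiosin), often placed at the preleptotene stage, are highest in LZ. PreL and LZ labels exchanged are argued against by the recombination list, whose median log2 fold change in LZ was 1.84 (1.838). RNA of PD or RS cells is argued against by their own levels, as Stra8 and Gm4969 stood at 0.0935% of their LZ level or less in every PD and RS library. Scaling is argued against by the log2 fold change of Stra8 of 2.22 (2.219) with total library size. What each sort gate held, and so how much of the preleptotene stage lies in LZ, was not tested and stays open. No biological explanation was tested.

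Almost every RS transcript stands in PD at a few percent of its RS level or more. RNA left from LZ is argued against, as X-linked genes active in LZ stood at most 0.998 times as high, in percent of RS, as those low in LZ. Reads of the whole pool under a wrong index are argued against by X-linked genes active in LZ, at a median of 0.399% of their LZ level in PD. RNA of RS cells at 1 share in each PD library is a candidate explanation, since the lowest 1st percentile of autosomal genes was 5.5% of the RS level. The interquartile range of the X-linked percentages was 0.324, 0.285 and 0.391 of their median in the 3 PD libraries. Counting alone would give 0.191, 0.23 and 0.21, so 1 share does not account for all of the spread. If RNA of RS cells is present in PD, the rises from PD to RS of genes silent in PD may be larger than measured. The floor is not particular to RS RNA in PD, since over 4495 genes of PD the 1st percentile in the 3 RS libraries was 4.9%, 6.91% and 11.9% of the PD level, and the falls from PD to RS are limited in the same way. Reads of RS libraries alone under the PD indexes, and low transcription in PD, stay open, and no biological explanation was tested.

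Other splits of the samples were fitted in the same way. For the 6 groups, 1 of 41 splits, the real one, gave as many differing genes (18365, highest other 1079). A random assignment of all libraries is thus argued against for the differences among groups as a whole. The enriched genes of each group numbered 0 in every other split. These splits mix very different groups, which leaves little room for enriched genes, so they cannot decide for the set of 1 group. For the 5 steps the 10 splits of 6 libraries are too few for a share under 0.05. For the genes higher and lower, given above, the highest other was 0, 1, 944, 0 and 0. The X-linked differences were −0.06, 0.34, 0.08, −5.72 and 3.07, with 0.04, 0.11, 0.13, 1.01 and 0.96 as the highest other in size, and 4 of 10 splits gave as large a value for PreL and LZ. For the lists called, given above, 7, 3, 8, 1 and 5 of 10 splits called as many. Between PreL and LZ, 3 other splits called 944, 781 and 860 genes, each with PreL replicate 2 and LZ replicate 2 on 1 side. A further split with both on 1 side, beside PreL replicate 1, called only 3, and the cause was not tested. The 3 other splits that part every numbered pair called 0.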
